A study of Mus musculus with 8 samples.

How the data were processed

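RNA was measured in 4 MYC-positive and 4 MYC-negative samples of sorted GC B cells. Per the labels' protocols, B cells were enriched with magnetic beads, GC B cells were sorted by GFP, and cDNA was amplified from 5 to 20 ng of total RNA with NuGEN kits, labelled with biotin and hybridised to Affymetrix arrays. The deposited values are probe set signal intensity on a linear scale, and MAS5 is the tool named in the submitters' processing notes. Its version and its scaling target are not given in the sources used here. The arrays had nearly the same mean signal after the lowest and highest 2% of values were trimmed, which ran from 497 to 498, so the values had been scaled array by array. No detection calls were used. The number of arrays, 4 per group, limits the precision.

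The table held 45056 probe sets, of which 19 were array controls. Genes were taken from the platform annotation provided with the series. Symbols were looked up by gene identifier in a RefSeq table of the mouse genome, which changed the symbol of 0 probe sets. This gave 34958 probe sets with 1 gene, 932 with several and 9160 non-control probe sets unnamed here. Probe sets with no or several genes were left out of the gene tests. No coordinates were used, because the files name no genome build.

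Signals below 1 were set to 1 and log2 was taken. Probe sets were kept where their mean log2 value over all arrays was above the 40th percentile of the non-control probe sets, a signal of 18.7. This kept 27022 probe sets, and the probe set with the highest mean was used for each of 11754 genes. The other kept probe sets of a named gene were compared with it: 50 of 119 named genes had any, and 5 had a probe set of opposite sign (Socs2, Ndufab1, Casp9, Psmd7 and Ccnd3). limma 3.58.1 in R 4.3.3 fitted the group with the pair as a block (lmFit, and eBayes with an intensity trend), which left 3 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested and called at an adjusted p under 0.05. Differences are MYC-positive minus MYC-negative on the log2 scale, and all tests were 2-sided. An exact sign-flip test over 4 pairs cannot give a p below 0.125, so no single-gene exact test was made. Where a pair does not stand for a separate animal, the p-values measure only the spread between these samples.

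The pairs come from the sample descriptions, which name each sample's partner. The replicate numbers in the titles, 1 to 4 and 4 to 7, were not used to pair samples. The pairing was checked by correlating paired samples' deviations from their group means over the genes tested, which gave 0.26, 0.17, 0.088 and 0.12 for pairs 1 to 4. Some arrays correlated more strongly with one outside their pair than with their partner. The MYC-negative array of pair 4 and the MYC-positive array of pair 3 both did so with each other (0.30). The MYC-positive array of pair 2 did so with the MYC-negative array of pair 1 (0.21). No 2 arrays held identical values, and correlations between arrays lay between 0.82 and 0.97.

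Before the data were examined, 34 gene lists were fixed with 1042 entries, of which 931 are on the array, along with the tests, the alternatives and the rule for named genes. Some genes are members of several lists, so the results of the lists are not independent. The rule took Myc, the 12 largest differences in each direction among called genes with the same sign in all 4 pairs, the 3 largest called members of each list, and 22 genes named in advance, of which 19 are analysed here. Lyz2, Apoe and the list members named only because a count was 5 or fewer were chosen after their values were seen: Ncapd2, Rbl1, Rbl2, Cdk6, Cdc25a, Cdk4, Lmo2, Fas, Lta, Jun, Foxp1, Exo1, Derl3, Ifi27, Oas3, Gadd45a, Rrm2b, Bad and Birc3. A total of 33 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit. A call lost there therefore does not by itself show that the members of a list are correlated. The granulocyte list had 1 measured member, which did not pass, and was not tested. At the preset correlation 19 lists passed, 18 higher and 1 lower. With an estimated correlation 0 passed, with a lowest adjusted p of 0.084. The fry test, which tests a list against no change and not against the other genes, and so follows the scaling, called 21. It did not call 2 of the 19, ribosomal proteins (adjusted p = 0.055) and control genes (0.12). It called 4 others: p53 targets (0.0048), uptake and mTORC1 genes (0.019), the dark zone (0.040) and naive and memory B cells (0.040).

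The procedure was tested on simulated arrays with the real means, pair effects and fitted spread, with 50 genes of 11754 changed by each of 4 sizes. It recovered 78% of genes raised by 2, 26% of those raised by 1, 24% of those lowered by 1 and 68% of those lowered by 2 on the log2 scale, with 2 false calls among 100. A list shifted by 0.5 was recovered, and 1 other list was called. The simulated genes varied independently of each other, while the estimated correlation within the measured lists reached 0.47, for ribosomal proteins. The simulation therefore cannot show how many calls are false where genes vary together. It gave 100 calls, against 2671 in the measured data. The Benjamini-Hochberg cutoff is looser where more genes pass, so the shares recovered do not carry over to the measured data.

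The alternatives were no block or a random block for the pair, no filter or a filter at the 60th percentile, quantile normalization, median centring, an offset of 2.38 (the 10th percentile) added before log2, the mean over probe sets, no probe sets with names ending in _s_at or _x_at, every probe set by itself, eBayes without a trend or robust, each pair left out, and a 1.5-fold minimum. Array weights were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.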

Results

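Germinal centre (GC) B cells, the antigen-activated B cells that divide and mutate their antibody genes in lymphoid follicles, were sorted from spleens of 8-week-old mice that carry a fusion of GFP to MYC at the Myc locus. The mice had been immunized with sheep red blood cells 12 days earlier. GC B cells were gated as binding peanut agglutinin (PNA) strongly and carrying much CD95 (the Fas receptor), and were parted by GFP into a MYC-positive and a MYC-negative fraction. RNA of 4 samples of each fraction was amplified and hybridised to Affymetrix mouse expression arrays, 8 arrays in all, and the sample descriptions name 4 pairs of a positive and a negative sample. The protocol describes the sort as done for each mouse and the design text speaks of pools, so whether a pair is a single mouse is not settled. The values were array signals that all shared about the same trimmed mean, from 497 to 498. Between 34.7% and 42.7% of the probe sets had a signal above 100 on an array. The comparison addresses how GC B cells sorted as positive for the GFP-MYC fusion differ from those sorted as negative.

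Myc itself was 2.83 higher on the log2 scale in MYC-positive than in MYC-negative samples (SE 0.28, n = 4 pairs, limma adjusted p = 0.00069), with a geometric mean signal of 663 against 92.9. The difference was between 2.58 and 3.44 in each of the 4 pairs. The cells had been sorted on the MYC fusion, so this difference checks the labels and is no finding. Of 11754 genes tested, 1319 were higher and 1352 lower in MYC-positive samples at an adjusted p under 0.05, and 1303 and 1320 of them had the same sign in all 4 pairs. The first principal component held 42.5% of the variance and placed all 4 MYC-negative arrays below 0 and all 4 MYC-positive arrays above it. The MYC-positive array of pair 4 lay farthest out on it, above the 31.1 that was the highest value of the other 7 arrays. The split between directions depended on the scaling: 49.4% of the called genes were higher as deposited, 57.2% after quantile normalization and 81.5% after centring each array on its median, and these scalings raised the median difference of all genes by 0.15 and 0.36. Median centring also raised the median of each list given below by 0.36. Without pair 1 the fit called 403 genes higher and 352 lower, without pair 2 it called 455 and 425, and without pair 4 it called 1742 and 2036. Of the genes named below as higher or lower, all had the same sign in 4 of 4 pairs except Cdk6, with the sign in 3 of 4.

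**Figure D1:**
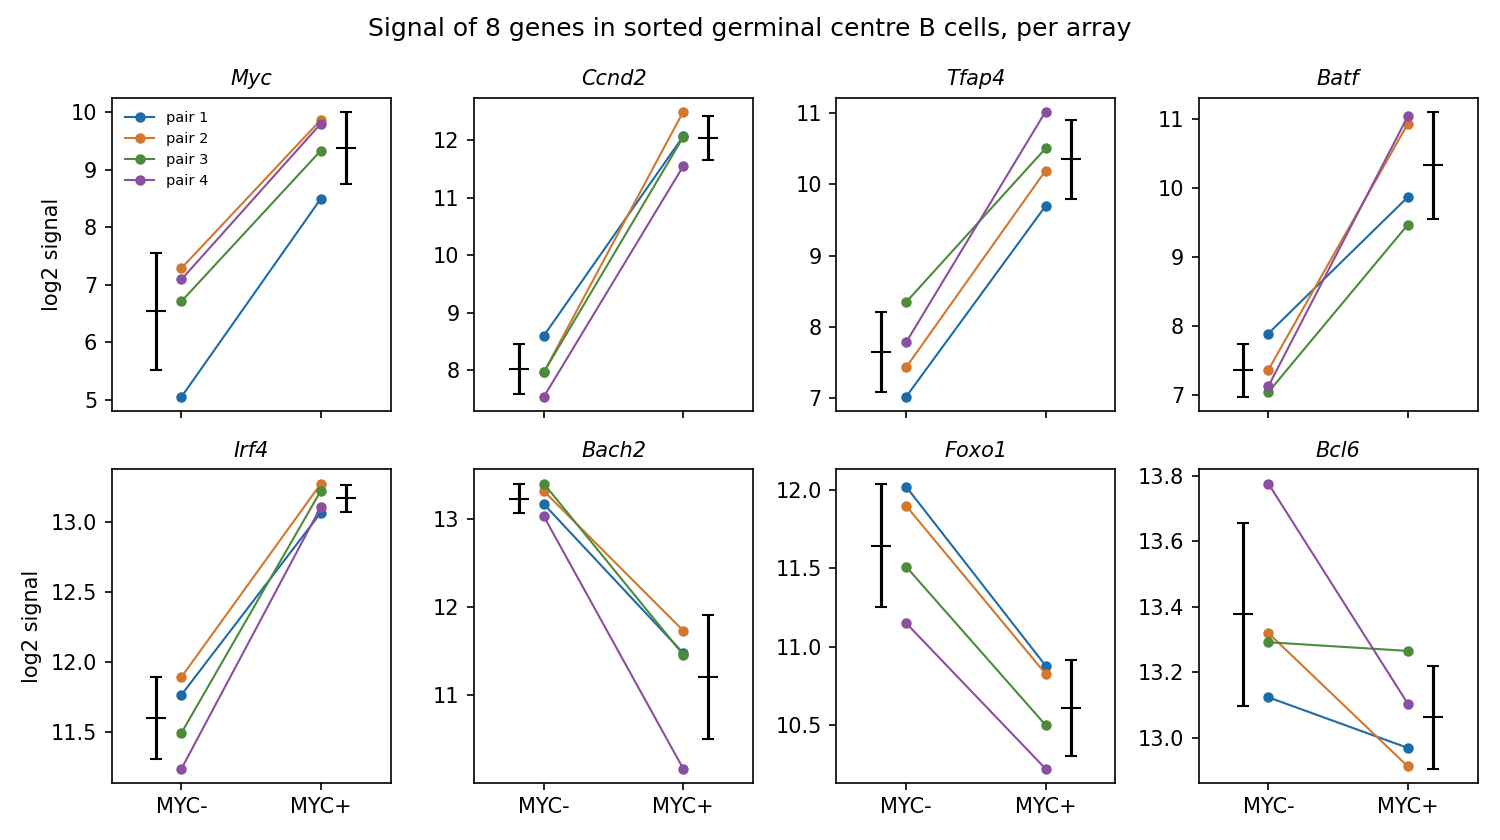
Log2 array signal (y axis) of 8 genes in the MYC-negative and MYC-positive sample of each pair (x axis), with a line per pair and, in black, the mean and SD of the 4 arrays of a group. Myc, Ccnd2, Tfap4, Batf and Irf4 were higher and Bach2 and Foxo1 lower in the MYC-positive sample of all 4 pairs, while Bcl6, at -0.32 on average as deposited and 0.044 after median centring, did not pass the test.

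Genes known as direct MYC targets and genes of ribosome production were higher in the MYC-positive fraction almost throughout. Of 37 MYC targets measured, 34 were higher and 0 lower (36 higher when adjusted over the list alone), with a median log2 difference of 1.11. The largest were Ccnd2, which encodes cyclin D2 (4.02, SE 0.21, adjusted p = 0.00018), Srm, the spermidine synthase gene (3.26, SE 0.22, adjusted p = 0.00035), and Tfap4, a transcription factor gene (2.70, SE 0.24, adjusted p = 0.00053). Of 59 genes of ribosome biogenesis, 54 were higher and 0 lower (58 higher when adjusted over the list alone), with a median of 1.25, led by the RNA polymerase I subunit gene Polr1b (2.31), Grwd1 (2.26) and the nucleolar GTPase gene Gnl3 (2.18). Of 41 genes of the ribosomal proteins themselves, 7 were higher and 0 lower (6 higher when adjusted over the list alone), with a median of 0.25 that was 0.084 after quantile normalization and 0.61 after median centring, while the list of control genes had a median of 0.29. Rpl12 (1.28) and Rpl14 (0.99) were among them. Rps25 (0.75) was too, with adjusted p = 0.053 without pair 1 and between 0.00024 and 0.078 over the alternatives. Of 36 translation factor and aminoacyl-tRNA synthetase genes, 29 were higher and 0 lower (30 higher when adjusted over the list alone), among them Eif2b3 (1.88) and Aimp2 (1.70). At an unadjusted p under 0.05, too, 0 members of these 4 lists were lower. With limma's camera test at a preset correlation of 0.01 these 4 lists stood above the other genes at adjusted p = 5.2e-24, 3.2e-31, 1.6e-07 and 2.5e-15. With an estimated correlation none of these calls held, at adjusted p = 0.10, 0.084, 0.38 and 0.10. The lists share members, such as Polr1b and Gnl3 in both the MYC target and the ribosome biogenesis list, so they are not separate lines of evidence. The myeloid marker list was also higher in the MYC-positive samples, with a median of 2.10.

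Metabolic, mitochondrial and proteasome lists, other than a list of uptake genes, were also higher by camera at the preset correlation, but not with an estimated one. Of 21 genes of purine and pyrimidine synthesis, 13 were higher and 1 lower (16 and 1 when adjusted over the list alone), including Umps (1.63, SE 0.22, adjusted p = 0.0020) and Cad (1.54, SE 0.20, adjusted p = 0.0018), which encode enzymes of pyrimidine synthesis (Umps was at 1.06 with the mean over probe sets). Of 14 genes of one-carbon metabolism and polyamine synthesis, 12 were higher and 0 lower (12 when adjusted over the list alone), including the serine hydroxymethyltransferase gene Shmt1 (2.50) and Mtap (1.32). Of 19 glycolysis genes 7 were higher and 0 lower (13 when adjusted over the list alone), including Hk2, which encodes a hexokinase (2.04), and Ldha, which encodes a lactate dehydrogenase subunit (1.14). Mitochondrial genes were higher in the MYC-positive samples for 26 of 38 members of the import, chaperone and mitochondrial ribosome list, with Timm10 at 1.89 and Timm9 at 1.83, and for 23 of 57 subunits of oxidative phosphorylation, with none lower in either list (31 and 32 higher when adjusted over each list alone). Proteasome and chaperonin genes were higher for 32 of 41 members and lower for 0 (41 higher when adjusted over the list alone), Ahsa1 at 1.24 among them (0.77 with the mean over probe sets). The folate carrier gene Slc19a1 (2.39) and the amino acid transporter gene Slc7a5 (1.89) were higher, but their list of uptake and mTORC1 pathway genes had 6 higher and 2 lower of 23 (7 and 2 when adjusted over the list alone) and did not pass the list test (adjusted p = 0.14). At an unadjusted p under 0.05, 1 glycolysis gene and 0 genes of the one-carbon, mitochondrial and proteasome lists were lower. The other 6 lists passed camera at the preset correlation, with adjusted p between 4.8e-17 for proteasome and chaperonin genes and 0.00012 for glycolysis. With an estimated correlation their adjusted p lay between 0.10 and 0.18, and the myeloid marker list, with its median of 2.10, moved in the same direction.

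Among cell cycle genes, the list of G1/S and DNA replication was higher by camera at the preset correlation but not with an estimated one. The list of mitosis passed neither. Of 48 genes of the G1/S transition and DNA replication, 10 were higher and 1 lower (10 and 1 when adjusted over the list alone), with a median of 0.28, where the list of control genes had 0.29. Ung, which encodes uracil-DNA glycosylase, was 0.86 higher (SE 0.13, adjusted p = 0.0036), and Pold2 (1.31) and Ccne1 (0.92) were higher too. Of 47 genes of G2/M and mitosis, 0 were higher and 4 lower (0 and 0 when adjusted over the list alone, and 1 and 11 at an unadjusted p under 0.05), with a median of -0.11 that became 0.25 after median centring. The 4 were Cenpe (-1.26), Kif23 (-0.58), Kif11 (-0.53) and Ncapd2 (-0.50). The proliferation marker gene Mki67 was at -0.27 (SE 0.17, adjusted p = 0.31), at -0.41 with adjusted p = 0.028 after quantile normalization and at 0.091 after median centring, and its adjusted p reached 0.81 without pair 4. Among 17 cyclin, kinase and inhibitor genes of G1, Ccnd2, Cdk6 (0.87), Cdc25a (0.84) and Cdk4 (0.78) were higher (5 when adjusted over the list alone). Cdkn2d (-1.20), Cdkn2c (-0.99), Rbl2 (-0.97), Cdkn1b (-0.73) and Rbl1 (-0.51), which encode inhibitors of G1 kinases or relatives of the retinoblastoma protein, were lower (6 when adjusted over the list alone). Ccnd3 was at 0.63 (SE 0.30, adjusted p = 0.16) and its other 2 probe sets at -1.33 and -1.32, and Cdkn1a was at 0.37 (SE 0.36, adjusted p = 0.50). The replication list passed camera at adjusted p = 3.8e-06 with the preset correlation and had adjusted p = 0.19 with an estimated correlation. The mitosis list did not pass (adjusted p = 0.21) but was called lower after quantile normalization, with a median of -0.15 and adjusted p = 0.0048 (up to 0.90 over the alternatives, after median centring). The G1 list did not pass (adjusted p = 0.62), and the myeloid marker list had a median of 2.10 in the same comparison. The calls of the 4 mitosis genes and of the 8 G1 genes other than Ccnd2 all ended without pair 1 and also without pair 2, with adjusted p up to 0.22 for Ncapd2 and 0.20 for Cdk6 (from 0.00013 to 0.63 for these 12 genes over the alternatives), while Kif23, Kif11, Ncapd2, Cdk6, Rbl2 and Cdkn1b also lost theirs without pair 3, with adjusted p up to 0.14, and Rbl1 without pair 4 (0.053). After median centring the 4 mitosis genes, Cdkn1b, Cdkn2c, Rbl1 and Rbl2 did not pass, with adjusted p from 0.075 to 0.57, and with the mean over probe sets Cdc25a was at 0.13, Ncapd2 at -1.19 and Rbl1 at -0.78. Cenpe was at -0.75 without pair 4. Pold2 had adjusted p = 0.050 without pair 1 and Ccne1 had 0.087 without pair 1 and 0.14 without pair 2 (from 0.00062 to 0.14 for both over the alternatives).

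Genes described as higher in light-zone GC B cells, the zone where B cells meet antigen and T cells, were higher for 10 of 27 members and lower for 2 (10 and 3 when adjusted over the list alone). After Ccnd2, the largest were Batf, a transcription factor gene (2.97, SE 0.34, adjusted p = 0.0011), and Ebi3, a cytokine subunit gene (2.17, SE 0.37, adjusted p = 0.0048). Irf4, which encodes a transcription factor of activated B cells and plasma cells, was 1.57 higher (SE 0.14, adjusted p = 0.00054). The members that were lower were Lmo2 (-0.48) and the chemokine receptor gene Ccr6 (-1.40). The light-zone surface marker genes Cd83 (0.17, SE 0.12, adjusted p = 0.34) and Cd86 (-0.03, SE 0.15, adjusted p = 0.92) did not pass, and Cd83 was at 0.53 with adjusted p = 0.041 after median centring and at -0.014 after quantile normalization. Of 31 genes of the NF-kB and CD40 response, 11 were higher, among them the NF-kB inhibitor gene Nfkbia (0.43), and 2, Fas (-0.61) and Lta (-1.20), were lower (12 and 3 when adjusted over the list alone). Immediate-early genes of antigen receptor signalling went both ways, with 3 of 25 higher and 6 lower (3 and 7 when adjusted over the list alone). Ier3 (3.50, with a MYC-negative signal under the filter level of 18.7 and differences from 1.73 to 6.69 in the 4 pairs), Nr4a3 (2.01) and the AP-1 gene Jun (1.11) were higher, Fos (-1.82), another AP-1 gene, was lower, and Egr1 was at -0.53 (SE 0.17, adjusted p = 0.052). The light-zone and NF-kB lists passed camera at adjusted p = 0.00046 and 0.011, and both had adjusted p = 0.18 with an estimated correlation. They share members, such as Ebi3, Irf4 and Nfkbia. The NF-kB list had a median of 0.30, where the list of control genes had 0.29. The immediate-early list did not pass (adjusted p = 0.88), and its median of -0.07, which became 0.29 after median centring, and its mean of 0.05 differed in sign. The myeloid marker list, with a median of 2.10, was higher in the same samples. Without pair 1 the calls of Lmo2, Ccr6, Nfkbia, Fas, Ier3, Jun and Fos ended, with adjusted p from 0.066 for Ier3 to 0.20 for Nfkbia, and without pair 2 all of these but that of Ier3, and that of Nr4a3, did, with adjusted p from 0.058 for Nr4a3 to 0.19 for Lmo2. Without pair 3, Ccr6, Nfkbia and Jun had adjusted p from 0.088 to 0.12. After median centring Lmo2, Fas and Ccr6 had adjusted p = 0.65, 0.30 and 0.077 and Nfkbia was at 0.79, and with the mean over probe sets Jun was at 0.63 and Nfkbia at 0.66. Ccr6 was at -0.86 without pair 3. Over the alternatives the adjusted p of these 8 genes lay between 0.00012 and 0.65, and Egr1 passed the threshold without pair 3 (adjusted p = 0.045) and after quantile normalization (0.0061).

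Genes of the GC programme were lower or not past the threshold. Of 26 measured, 0 were higher and 6 lower (0 and 7 when adjusted over the list alone, and 0 and 15 at an unadjusted p under 0.05), with a median of -0.32 that became 0.04 after median centring. Mybl1, which encodes a MYB-family transcription factor, fell by 2.12 (SE 0.23, adjusted p = 0.00088). Bach2, which encodes a transcriptional repressor that holds back plasma cell differentiation, differed by -2.02 (SE 0.21, adjusted p = 0.00080) and Pax5, a B cell identity gene, by -1.75 (SE 0.38, adjusted p = 0.012). The only kept probe set of Pax5 was dim, with a signal of 148 in MYC-negative and 44.2 in MYC-positive samples. In the MYC-positive array of pair 4 its log2 signal was 3.69, under the filter level of 4.22, so the fold of Pax5 is poorly determined. Bcl6, the master regulator gene of GC B cells, was at -0.32 (SE 0.14, adjusted p = 0.13), and S1pr2, which encodes a receptor that holds B cells in the GC, at -0.33 (SE 0.13, adjusted p = 0.10). Of 19 genes described as higher in dark-zone cells, where GC B cells divide and mutate, 2 were higher, Ung and Exo1 (0.79), and 5 lower (2 and 6 when adjusted over the list alone). The 5 were Mybl1, Bach2, Pafah1b3 (-1.86), Foxo1, which encodes a transcription factor of dark-zone cells (-1.04, SE 0.14, adjusted p = 0.0023), and Foxp1 (-0.85). Foxo1 was at -0.68 and Foxp1 at -0.50 after median centring, and Foxp1 at -1.64 with the mean over probe sets. The dark-zone chemokine receptor gene Cxcr4 was at -0.30 (SE 0.12, adjusted p = 0.10). With the mean over its probe sets, the other of which was at -1.32, Bcl6 was at -0.82 and passed the test (adjusted p = 0.0036). Bcl6, S1pr2 and Cxcr4 also depended on the scaling, with -0.48, -0.46 and -0.47 after quantile normalization, where they passed the test (adjusted p = 0.0026, 0.011 and 0.0035), and 0.044, 0.032 and 0.062 after median centring, where adjusted p was 0.88, 0.91 and 0.81. The GC list passed camera at adjusted p = 0.00092, and had adjusted p = 0.18 with an estimated correlation. The dark-zone list did not pass (adjusted p = 0.36), with a median of 0.04 against a mean of -0.29. After quantile normalization it was called lower (median -0.0018, adjusted p = 0.021, from 0.021 to 0.63 over the alternatives). The myeloid marker list had a median of 2.10 in the same samples. Pax5 had adjusted p = 0.056 without pair 1 and 0.058 without pair 2, and Exo1 0.11 and 0.13 (from 0.00021 to 0.15 for both over the alternatives).

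Plasma cell and naive or memory B cell genes were the last of the B cell groups. Of 16 plasma cell genes, Sdc1, the gene of the surface marker CD138 (2.02), Slpi (1.83, SE 0.14, adjusted p = 0.00041), Irf4 and Derl3 (1.16) were higher and 0 lower (4 and 0 when adjusted over the list alone, and 4 and 1 at an unadjusted p under 0.05). Their median was 0.14, where the list of control genes had 0.29. Prdm1, the regulator gene of plasma cell differentiation, was at 0.54 (SE 0.32, adjusted p = 0.26), and at 0.92 with adjusted p = 0.046 after quantile normalization (up to 0.65 over the alternatives). The plasma cell list passed at adjusted p = 0.044, but had adjusted p = 0.37 after quantile normalization, adjusted p = 0.066 without pair 4, adjusted p between 0.072 and 0.099 without the filter, with a stricter filter, with the mean over probe sets and with array weights, and adjusted p = 0.19 with an estimated correlation (from 0.012 to 0.37 over the alternatives). Of 19 naive and memory B cell genes 0 were higher and 7 lower (1 and 7 when adjusted over the list alone, as at an unadjusted p under 0.05), the transcription factor gene Hhex (-1.65, SE 0.25, adjusted p = 0.0032) among them. That list did not pass (adjusted p = 0.11), though it did without pair 4 (adjusted p = 0.029) and with array weights (0.033), against up to 0.30 over the alternatives, and its median of -0.24 became 0.12 after median centring. The myeloid marker list, with a median of 2.10, was higher in the same samples. Without pair 2, Sdc1 had adjusted p = 0.050 and Derl3 0.14, which had 0.14 without pair 1 too (from 3.9e-05 to 0.14 for both over the alternatives).

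The 12 largest differences in each direction were mostly of genes with very low signal in a fraction. Csf1r, the macrophage growth factor receptor gene, was 6.40 higher in MYC-positive samples (SE 0.70, adjusted p = 0.00093), and Vcam1, an adhesion molecule gene, 5.98 higher (SE 0.40, adjusted p = 0.00035). Next came Lpl (5.85), the iron exporter gene Slc40a1 (5.83), the complement genes C1qc (5.10) and C1qa (5.07), Saa3 (4.80), Spire1 (4.76), Socs2 (4.67), Retnla (4.57), Fn1 (4.35) and Adgre4 (4.31). In 10 of the 12, the mean signal of the MYC-negative samples lay under 18.7, the level of the filter on dim probe sets, so these folds are poorly determined. With the mean over the probe sets of a gene, Csf1r was at 3.84, Vcam1 at 3.89, Spire1 at 2.82 and Socs2 at 2.03. Socs2 was at 1.98 with adjusted p = 0.058 when probe sets ending in _s_at or _x_at were left out. The largest lower genes were Lgr5 and Adgb, both at -5.00, Gcnt3 (-4.13), Grm5 (-4.07), Tbx6 (-4.06), Crisp3 (-3.95), 4933406C10Rik (-3.95), G530011O06Rik (-3.89), Tsnaxip1 (-3.77), 4930578M01Rik (-3.76), Dnah8 (-3.74) and Gm30054 (-3.57). The signal in MYC-positive samples was under 18.7 for 8 of these 12. Gcnt3, which encodes a glycosyltransferase, had a signal of 2021 in MYC-negative and 116 in MYC-positive samples. Tbx6 had adjusted p = 0.062 without pair 1 and Tsnaxip1 had 0.052 in a fit without the intensity trend (from 6.7e-07 to 0.062 for Socs2, Tbx6 and Tsnaxip1 over the alternatives).

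Markers of cell types that the gate should not hold were also measured. Of 21 myeloid markers, 13 were higher and 1 lower in the MYC-positive samples (15 and 1 when adjusted over the list alone), with a median of 2.10. The array holds 28 of these markers, and the filter kept the 21. In 8 of the 21 the mean MYC-negative signal lay under 18.7. Those 8 passed the filter only through the MYC-positive samples, which can raise the median. Over the alternatives the median lay between 1.53 and 2.51. The mean over the list was between 1.48 and 3.43 in each of the 4 pairs. Besides Csf1r, Vcam1, Slc40a1 and the complement genes, Lyz2, the lysozyme gene, was 3.40 higher (SE 0.32, adjusted p = 0.00058), while the apolipoprotein gene Apoe was lower, at -1.87. The list passed camera at adjusted p = 2.6e-08, and had adjusted p = 0.18 with an estimated correlation. Of 7 T cell markers Thy1 (2.34, with a MYC-negative signal under 18.7) was higher, and Cd2 (-0.85) and Lat (-2.12) were lower (1 and 2 when adjusted over the list alone). Cd2 had a signal of 2418 in MYC-positive and 4361 in MYC-negative samples. At that level a small share of T cells would be hidden. Of 5 natural killer cell markers Ccl5 (3.34, with a MYC-negative signal under 18.7) was higher and 0 lower (1 and 1 when adjusted over the list alone). Of 5 erythroid and platelet markers Hbb-b2 (2.01) was higher and 0 lower (1 and 0 when adjusted over the list alone). Of 11 stromal markers, Vcam1, which the myeloid list holds too, was higher and Pecam1 (-1.97) lower (1 and 1 when adjusted over the list alone). None of these 4 lists passed, with adjusted p from 0.56 to 0.74, and the median and mean differed in sign for natural killer cells (-0.02 and 0.56) and stroma (-0.26 and 0.14). The T cell, natural killer cell and stromal medians were above 0 after quantile normalization and after median centring. Of 10 control genes, Gusb (0.79) was higher and 0 were lower (3 higher when adjusted over the list alone). The control list had a median of 0.29 (adjusted p = 0.028), with adjusted p = 0.53 after quantile normalization, adjusted p = 0.18 without pair 3, adjusted p between 0.051 and 0.098 with no or a random block, a stricter filter and the mean over probe sets, and adjusted p = 0.44 with an estimated correlation (from 0.0064 to 0.53 over the alternatives). Without pair 1, Thy1, Lat, Hbb-b2, Apoe and Gusb had adjusted p = 0.062, 0.075, 0.092, 0.054 and 0.12, and without pair 2 Thy1, Hbb-b2, Apoe, Gusb and Cd2 had 0.063, 0.11, 0.064, 0.098 and 0.061 (from 3.4e-05 to 0.12 for these 6 genes over the alternatives). Cd2 was at -0.49 with adjusted p = 0.066 after median centring.

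**Figure D2:**
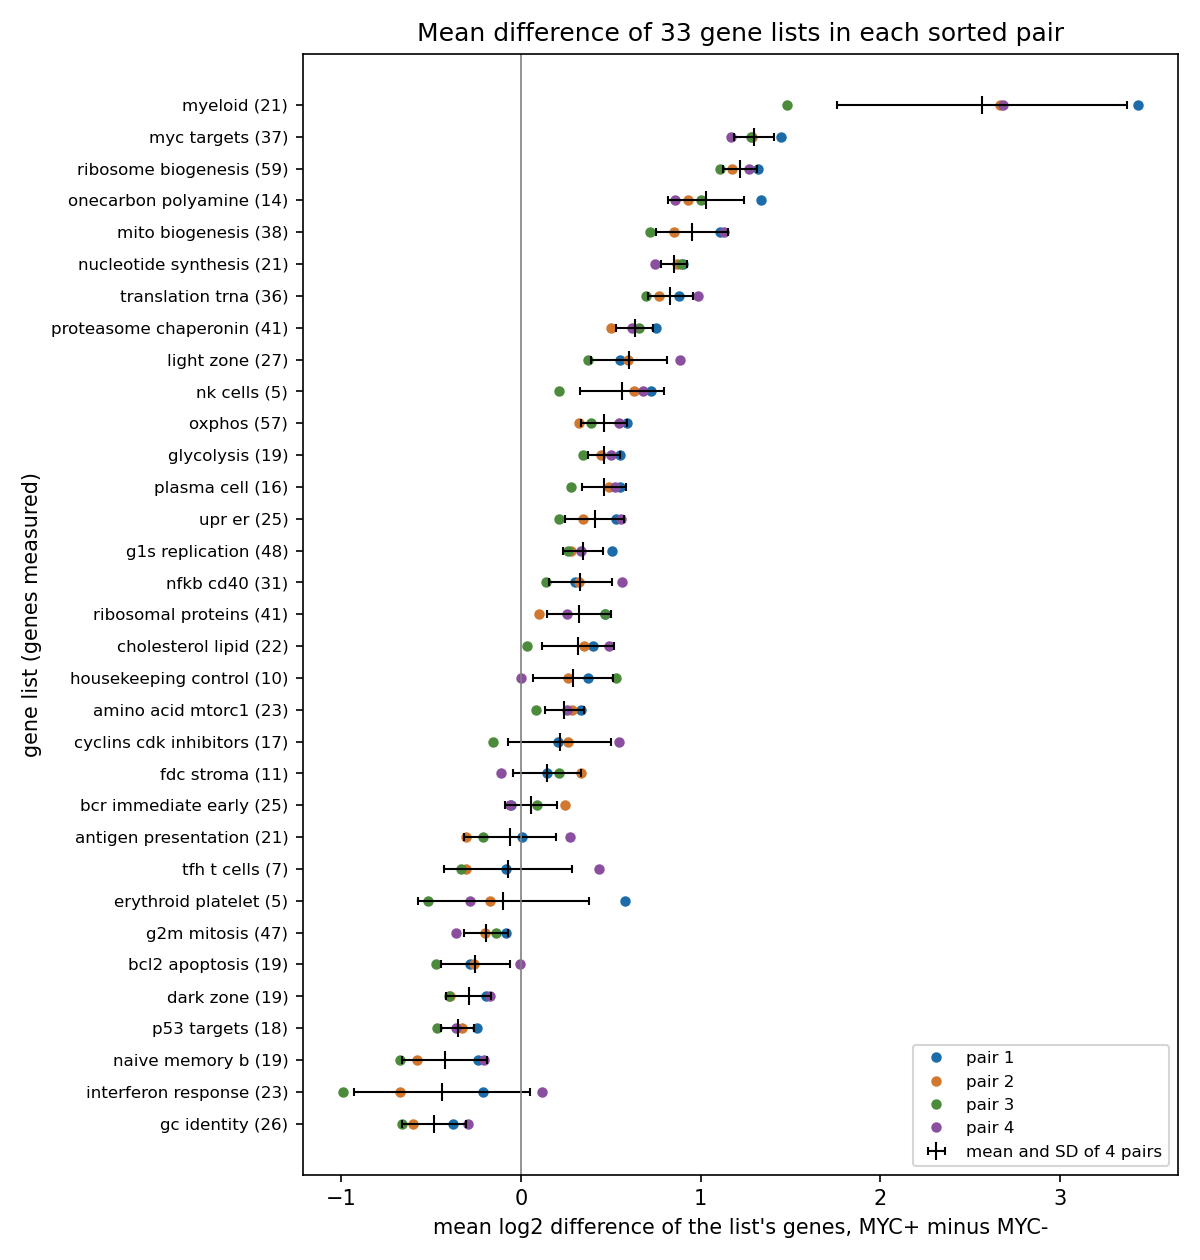
Mean log2 difference, MYC-positive minus MYC-negative (x axis), over the measured genes of 33 gene lists (y axis, genes measured in brackets), with a point for each of the 4 pairs and, in black, their mean and SD. The myeloid markers lay highest, between 1.48 and 3.43, the MYC targets between 1.17 and 1.45, and the GC programme below 0 in all 4 pairs, though its median became 0.04 after median centring.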

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

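The tests of array scaling and of a lower B cell share for the myeloid markers, of array scaling and of matched silent gene families for the unnamed probe sets, and of RNA degradation and a wrong label for the MYC-positive array of pair 4 were chosen after the result was seen.

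Myeloid markers were higher in the MYC-positive samples by a median of 2.10, and 7 of the 21 measured had a signal above 100 in MYC-negative samples as well. Array scaling is argued against by the median of 2.43 after quantile normalization, with pair means from 2.05 to 3.53. For a lower share of GC B cells that raises all other cell types alike, 27 T cell, NK cell, stromal and erythroid markers were pooled, with Vcam1 left out. Their median as deposited was -0.26 (95% bootstrap interval -0.56 to -0.07, with markers taken as independent), below the bound of 1.05 set from the myeloid median. Only 7 of the 27 had a MYC-negative signal above 100, the bright Cd2 among them. Dim markers can stay flat whatever the share of their cells, so this argues only weakly against such a rise. RNA of macrophages carried into the MYC-positive sort is a candidate explanation: a further list of 33 macrophage genes, written before their values were seen, had a median of 0.43, above the highest (0.41) of 10000 random lists of matched signal, with 8 genes higher, such as Mrc1 (2.11) and Cd5l (1.81), and 3 lower. Against it as the whole account stand Apoe, with a signal of 134 in MYC-positive and 490.3 in MYC-negative samples, and from that list Abca1 (102 and 469) and Tlr4 (199 and 564), while Fth1 (16348 and 15667), Cst3 (5191 and 6546) and Selenop (4308 and 8227), the third lower gene, are so high in both that a small share would be hidden. The magnetic B cell isolation and the GC gate would remove most macrophages, and transcription of these genes in MYC-expressing cells themselves was not tested and stays open. The random lists held unrelated genes, so a median above theirs does not single out macrophage RNA. The light-zone list also had a median of 0.43, and the control list had 0.29. Of all 11754 genes tested, 1319 were higher and 1352 lower, where the macrophage list had 8 and 3 of 33.

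The 4331 kept probe sets with no gene in the tables used here, which the report's comparisons leave out, were lower in the MYC-positive samples by a median of -0.85, and lay -0.57 below named probe sets of the same signal, between -0.93 and -0.25 in the 4 pairs. Array scaling is argued against by a gap of -0.57 after quantile normalization, between -0.92 and -0.28 in the 4 pairs. Genomic DNA carried into the MYC-negative samples is argued against by 26 probe sets of gene families silent in B cells, which had a gap of 0.068 to named probe sets; they are dim, but lay 0.49 above unnamed probe sets matched to their signal (95% bootstrap interval 0.17 to 0.82, 0.13 to 1.00 in the 4 pairs), which themselves had a gap of -0.38. A lower share of nuclear RNA in MYC-positive cells cannot be told apart, since 32 probe sets of nuclear transcripts had a gap of -0.29 with an interval from -0.72 to 0.07, and values from -1.04 to 0.12 in the 4 pairs. The interval treats probe sets as independent, though several belong to the same gene, and the genes differed. Those of Malat1 had gaps from -2.16 to -0.94, and those of Airn, which were dimmer, from 0.67 to 2.18. A difference between the sorted cells in transcription outside the named genes was not tested and stays open.

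The MYC-positive array of pair 4 stood apart from the other MYC-positive arrays, with a mean correlation of 0.893 as deposited, where the lowest of the other 3 was 0.924. Array scaling is argued against by the correlation of 0.879 after quantile normalization, with the others from 0.918 to 0.933. RNA degradation is argued against by the ratio of 3' to 5' signal of Actb, which was 1.92 where the other 7 arrays had 1.43 to 2.24, and of Gapdh, 1.37 where they had 1.35 to 1.57. A wrong label is argued against by its Myc signal of 891, where the highest MYC-negative array had 156. Differences in amplification stay open, and no biological explanation was tested.

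Of 304 groups of 4 arrays, formed from the named genes and the list means, 22 held an array far from the other 3, or 7.24%, where chance gives about 5% and the genes are not independent. Of the 22, 11 lay in pair 4. The values that follow are log2 signals, with the range of the other 3 arrays of the group. In the MYC-negative array of pair 1, Polr1b was at 4.82 (others 6.20 to 6.35), Grwd1 at 9.18 (9.73 to 9.84), Timm10 at 9.80 (10.00 to 10.04) and the mean of the unfolded protein response list at 10.33 (10.58 to 10.61). In that of pair 2, Saa3 was at 4.88 (6.08 to 6.23), Creld2 at 9.83 (9.65 to 9.67) and Ahsa1 at 10.66 (10.26 to 10.31). In that of pair 4, Tbx6 was at 3.72 (6.90 to 7.47), Hk2 at 8.77 (9.41 to 9.51), Hhex at 9.40 (10.22 to 10.34), Pecam1 at 6.54 (7.64 to 7.77) and Ccr6 at 7.50 (9.13 to 9.41), the T cell list at 5.74 (6.38 to 6.43) and the control list at 12.87 (12.27 to 12.36). In the MYC-positive array of pair 1, Adgre4 was at 9.11 (7.56 to 7.81) and Tsnaxip1 at 1.02 (4.70 to 5.21), in that of pair 2 Lat was at 5.38 (3.80 to 3.93), and in that of pair 3 Impdh1 was at 6.16 (7.07 to 7.25). In that of pair 4, Grwd1 was at 12.24 (11.73 to 11.81), Cenpe at 7.91 (10.12 to 10.44), the oxidative phosphorylation list at 12.82 (12.32 to 12.40) and the proteasome list at 12.88 (12.630 to 12.636).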

How the results depend on the processing

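Array weights and the counts over other splits of the arrays were chosen after the data were seen, and the other alternatives were planned. The difference in Myc stayed past the threshold under all of them, between 2.63 and 3.19. The 1319 higher and 1352 lower genes became 2758 and 627 after median centring, 736 and 771 without the intensity trend, 1989 and 2649 with every probe set tested by itself, and 2127 and 2433 with array weights. With no replicate block for the pair they were 1055 and 901. Leaving out a pair gave between 403 (without pair 1) and 1742 (without pair 4) higher, and between 352 and 2036 lower genes. With every probe set by itself more tests were made, and the other causes were not tested. The remaining settings stayed within 1.5 times both counts.

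Of the 108 named genes past the threshold other than Myc, 57 passed in the same direction under every alternative that gave a value, and the other 51 lost the call under at least 1, none with a change of sign. Without pair 1, 42 lost the call, without pair 2, 37, without the intensity trend 26, with no replicate block 15, after median centring 12, with the mean over probe sets 10, without pair 3, 9, and under any other setting at most 6. The genes named by the rule that changed sign had not passed. After median centring these were Bcl6 (0.044), Cxcr4 (0.062), Cd86 (0.33), Mki67 (0.091) and S1pr2 (0.032). Cd83 was at -0.014 after quantile normalization and Ccnd3 at -0.67 with the mean over probe sets. Birc3, which had passed, was at -0.022 with the mean over probe sets. Cd86 lay between -0.13 and 0.038 with a pair left out.

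With an estimated correlation none of the 19 lists kept its call. That version of camera uses the 3 residual degrees of freedom, so the losses cannot be laid to correlated members alone. The unfolded protein response, glycolysis and plasma cell lists lost their calls with estimated correlations of 0.0088, -0.035 and -0.023, below the preset 0.01. Medians that changed sign after median centring were those of mitosis (0.25), immediate-early genes (0.29), the GC programme (0.038, still called lower than other genes), naive and memory B cells (0.12), apoptosis (0.060), p53 targets (0.18), T cells (0.20), NK cells (0.34) and stroma (0.097). After quantile normalization they were the dark zone (-0.0018), antigen presentation (-0.13), T cells (0.27), NK cells (0.39) and stroma (0.029). Others were G1 cyclins and inhibitors without the filter (-0.073), antigen presentation with the mean over probe sets (-0.018), without _s_at and _x_at probe sets (-0.0017) and with array weights (-0.079), and the dark zone with array weights (-0.019). With a pair left out, medians lay between -0.096 (without pair 4) and 0.086 for the dark zone, -0.034 and 0.14 for immediate-early genes, -0.046 and 0.097 for antigen presentation, -0.35 and 0.25 for T cells and -0.29 and 0.20 for NK cells. The causes were not tested. Signals near the filter level of 18.7 limit the folds of dim genes.

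Whether an arbitrary division of the arrays gives as many genes was asked with other splits. With the pair as a block, as in the report, 8 splits part all pairs, too few for a share under 0.05; the real one gave 2671 genes and the highest other 0. In a fit that ignores the pairs, the real split gave 1956 genes and the highest of the other 34 gave 0, so that 1 of 35 splits was as large; most of them put both samples of some pair on the same side, so they do not stand in for splits of paired samples.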

Other observations

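No test in this part was chosen after a result was seen, apart from the fit with array weights and the naming of single list members given in the methods. Lists of secretory and lipid synthesis genes were also higher in the MYC-positive fraction by camera at the preset correlation, but not with an estimated one. Of 25 genes of the unfolded protein response and endoplasmic reticulum, 10 were higher in MYC-positive samples and 1 lower (12 and 1 when adjusted over the list alone), with a median of 0.40. They included Sdf2l1 (1.46), the disulfide isomerase gene Pdia6 (1.06) and Creld2 (0.99), whose calls all ended without pair 1, with adjusted p from 0.058 to 0.069, and those of Pdia6 and Creld2 without pair 2, with 0.072 and 0.058 (from 0.00016 to 0.072 over the alternatives). The list passed camera at adjusted p = 0.00012, and had adjusted p = 0.11 with an estimated correlation. Of 22 genes of cholesterol and fatty acid synthesis, the fatty acid synthase gene Fasn (1.15), Acaca (0.93) and Idi1 (0.70) were higher and 0 lower (3 and 0 when adjusted over the list alone, and 8 and 0 at an unadjusted p under 0.05). Without pair 1 these 3 had adjusted p = 0.067, 0.15 and 0.19, without pair 2 they had 0.083, 0.13 and 0.13, without pair 3 Idi1 had 0.065, and with the mean over probe sets Acaca had 0.21 (from 0.00011 to 0.21 over the alternatives). That list passed at adjusted p = 0.0096, and had adjusted p = 0.12 after quantile normalization, adjusted p = 0.082 with the mean over probe sets and adjusted p = 0.19 with an estimated correlation. Its median was 0.25, where the list of control genes had 0.29, and of all 11754 genes tested 1319 were higher. In the same samples the myeloid marker list was higher by a median of 2.10.

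None of the lists of p53 targets, apoptosis, interferon response and antigen presentation passed camera. Of 18 p53 targets 0 were higher and 5 lower (0 and 5 when adjusted over the list alone, and 3 and 6 at an unadjusted p under 0.05), with a median of -0.18 that became 0.18 after median centring. Trp53inp1 was at -1.67 (SE 0.12, adjusted p = 0.00035), the antiproliferative gene Btg2 at -1.35, Sesn1 at -1.02, Gadd45a at -0.94 and Rrm2b at -0.66. Of 19 genes of the BCL2 family and apoptosis, Bid (0.79) and Birc3 (0.60) were higher and 4 lower (2 and 6 when adjusted over the list alone), with a median of -0.30 that became 0.060 after median centring. Bcl2l11, the gene of the death-promoting protein BIM, was at -1.27 (SE 0.15, adjusted p = 0.0012), and Casp9 (-0.62), Fas (-0.61) and Bad (-0.59) were the others. Of 23 interferon response genes Cxcl10 (1.58) was higher, and Oasl2 (-2.59, with a MYC-positive signal under the filter level of 18.7), Ddx58 (-1.63), Oas3 (-1.36) and Ifi27 (-0.71) were lower (2 and 7 when adjusted over the list alone), with a median of -0.57. Of 21 antigen presentation genes 0 were higher, and Ciita (-0.76), the regulator gene of MHC class II, and H2-Ob (-0.56) were lower (0 and 1 when adjusted over the list alone, and 0 and 3 at an unadjusted p under 0.05), with a median of 0.02 that became -0.13 after quantile normalization and a mean of -0.06. The adjusted p of the 4 lists was 0.12, 0.14, 0.063 and 0.96. The interferon list was called lower without pair 1 (adjusted p = 0.042), without pair 4 (0.0077), with array weights (0.0083), with the stricter filter (0.018), after median centring (0.020) and without the filter (0.041), and had adjusted p = 0.54 with an estimated correlation. Antigen presentation was called lower after quantile normalization (0.021, up to 0.99 over the alternatives), and the p53 list without the filter (0.041, up to 0.28 over the alternatives). Without pair 2 the calls of all genes named here but Trp53inp1 and Bcl2l11 ended, with adjusted p from 0.052 for Oasl2 to 0.21 for Ciita (from 3.2e-05 to 0.95 over the alternatives). Without pair 1 those of the same genes but Sesn1 ended, with adjusted p from 0.051 for Oasl2 to 0.18 for Ciita, and without pair 3 those of Birc3, Bad, Ifi27, Ddx58 and Ciita, with adjusted p from 0.066 to 0.13. After median centring Rrm2b, Gadd45a, Casp9, Fas, Bad, Ddx58, Ifi27, Ciita and H2-Ob did not pass, with adjusted p from 0.052 to 0.43, and Sesn1 was at -0.67. With the mean over probe sets Trp53inp1 was at -2.60, Rrm2b at -1.26, Casp9 at -0.18 and Birc3 at -0.022.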
